A study of Homo sapiens with 128 samples.

How the data were processed

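Gene expression was measured in 128 human cervical specimens on Affymetrix U133 Plus 2.0 arrays. Per the labels' protocols, biopsies were flash frozen and cryosectioned, epithelium or tumour was captured by laser in 120 specimens, 8 cancers were taken as whole sections, and total RNA was carried through linear amplification before hybridization. The deposited values are log2 expression values that the authors made with GC-RMA, per the submitters' processing notes, and no version is given there. The table held 54675 probe sets with values from -0.89 to 16.98. No 2 arrays had identical columns, and the correlation between arrays ranged from 0.545 to 0.975.

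Probe sets were named from the annotation supplied with the reference: 41097 carried 1 gene symbol, 1801 carried several and were not used here, and 11777 were not named here. Each of 19740 genes was represented by the probe set with the highest mean over all arrays (10511 genes had more than 1). Genes with a log2 value of 4 or more in at least 14 arrays were tested, which left 12840. XIST and Y-linked genes were not used here.

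The groups were those of the labels: 24 normal, 14 CIN1, 22 CIN2, 40 CIN3, 20 laser-captured cancers and 8 whole-section cancers. The comparisons, tests, filter, gene lists, naming rule and a first set of alternatives were chosen before the data were examined. Each of 8 comparisons was fitted on its 2 groups alone with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, called at an adjusted p under 0.05). List scores were the mean log2 value over the tested members of a list in each array. There were 31 lists with 604 different genes, of which 518 were tested. Scores were compared by permutation with 100000 resamples, or by exact enumeration where a group had under 10 arrays, and adjusted over the lists within a comparison. With 100000 resamples the smallest possible p is 1e-05. Lists were also tested with camera in limma with a correlation between genes estimated from the data. Camera asks whether the genes of a list changed more than the other genes tested. The permutation test asks only whether the list score differs between groups, and that score already carries the correlation between genes. Its p grows with the estimated correlation. A call lost there thus does not show that the list changed no more than other genes. Nor does it mean that correlation overturned the permutation test.

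Genes were named by a rule: in each comparison the 6 largest and the 6 smallest log2 folds among called genes with a mean of log2 6 or more in the higher group, up to 4 members of each described list with the smallest adjusted p (or 2 members as values where none was called), and CDKN2A, MKI67, TOP2A, ESR1, CXCL14 and KRT13 throughout. Not every gene that the rule names is printed. The same choice was also made from the fit with the array-set block, and that addition came after the values had been seen.

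The 3 array sets were found after the data had been opened and are not in the labels. A control probe set for thr read 2.76 or more in set 1 and 2.39 or less in the others. Sets 2 and 3 were separated by a principal component of 18061 probe sets near the floor, which held 14.7 percent of their variance and had a gap of 1.56 SD, and a control for trpn read 2.21 or more in set 2 and 2.17 or less in set 3. Array set was then added as a block to the 2-group fits and to a fit of all 6 groups, list labels were permuted within array sets, and each set was fitted alone where both groups had at least 3 arrays in it. These fits were chosen after the first results had been seen.

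Other alternatives were: no low-value filter and a stricter filter (log2 6, 11048 genes), the mean of all probe sets of a gene, all 6 groups in 1 fit, eBayes with trend and robust, array weights, a further quantile normalization, arrays shifted to an equal median, the replicate number as a block, covariates for RNA quality and for other cell types, the Wilcoxon rank-sum test, all 28 cancers together, and fits without Normal replicate 24 or without the 8 arrays whose median correlation with their own group was under 0.8. Labels were also split at random 99 times in each comparison.

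The fits were tested on simulated data with 12840 genes, of which 100 were changed by log2 1 and 100 by log2 2. With array-set differences as measured, the 2-group fit made 1439 false calls in the layout of CIN3 against normal tissue, 637 for laser-captured cancer against normal tissue and 249 for CIN3 against CIN2, and the fit of all 6 groups with the block made 5, 13 and 12. Simulated genes varied independently and had the same set differences in every group, which is what the block assumes. The low counts therefore do not show how it behaves with correlated genes. Labels of the real arrays were also split within array sets. The 2-group fit with the block then called at most 460 genes for CIN3 against CIN2. It called at most 243 for laser-captured cancer against normal tissue and 170 for CIN2 against CIN1. In the simulation the fit of all 6 groups with the block recovered 46 of 100 changes of log2 1 and 93 of 100 changes of log2 2 for CIN3 against normal tissue, 57 and 89 for CIN1 against normal tissue, 38 and 86 for CIN2 against CIN1, and 35 and 80 for whole-section against laser-captured cancers. Changes of log2 1, and smaller ones, may thus often have been missed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.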

Results

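The series profiled the epithelium of the human cervix from normal tissue to invasive cancer on Affymetrix U133 Plus 2.0 arrays. Frozen biopsies had been sectioned. In 120 specimens the epithelium or tumour was dissected with a laser before RNA extraction. These comprised 24 normal specimens, 14 low-grade lesions (cervical intraepithelial neoplasia grade 1, CIN1), 22 lesions of grade 2 (CIN2), 40 of grade 3 (CIN3) and 20 squamous cancers. A further 8 squamous cancers were taken as whole sections, stroma included. Values are log2 expression per gene, for 12840 genes that reached the filter on low values. The labels do not say whether each specimen came from a separate woman, so p-values measure the spread between specimens, and the number of arrays in each group limits the precision.

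The arrays fell into 3 sets that the labels do not name, found from control probe sets and from probe sets near the background. Set 1 held 29 arrays, set 2 held 39 and set 3 held 60. The upper quartile of all probe sets was 6.42 ± 0.18 (SD) in set 1, 7.46 ± 0.21 in set 2 and 7.54 ± 0.22 in set 3. The groups were spread unevenly over them: normal arrays lay in sets 1 (7) and 2 (17), whereas 31 of 40 CIN3 arrays and 14 of 20 laser-captured cancers lay in set 3, which held no normal array. Within the normal group alone, 5776 of 12840 genes differed between sets 1 and 2, and within CIN2 1175 differed between sets 2 and 3. The main results below are therefore given as fitted on the 2 groups alone (the 2-group fit) and with array set as a block, in a fit of all 6 groups that is called the blocked fit from here on. List scores were also tested with labels permuted within array sets. Only sets that hold both groups enter that test, so no array of set 3 enters a comparison with normal tissue. For CIN3 against normal tissue it uses 7 and 7 arrays of set 1, and 2 CIN3 and 17 normal arrays of set 2. For laser-captured cancer against normal tissue it uses 4 cancers and 7 normal arrays of set 1, and 2 and 17 of set 2.

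**Figure D1:**
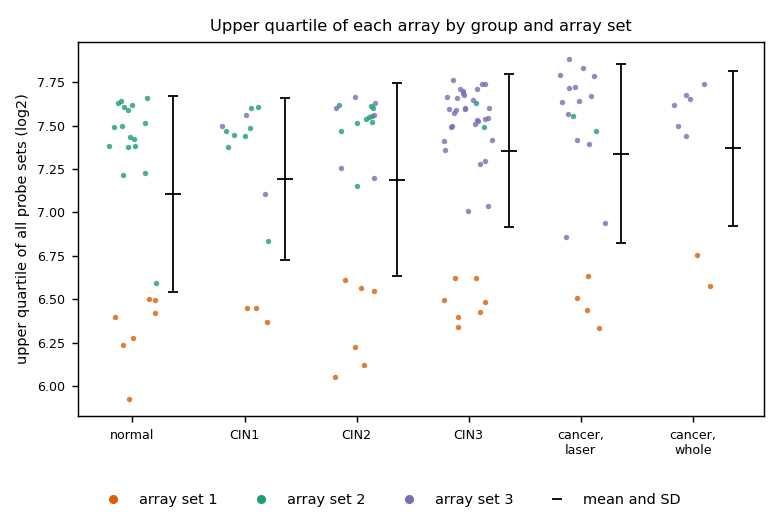
Upper quartile of all probe sets (log2, vertical axis) for each array, by group (horizontal axis) and coloured by array set, with the group mean and SD beside the points. The 29 arrays of set 1 lie between 5.92 and 6.76, and the arrays of set 3 between 6.86 and 7.89.

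The first comparison asked what distinguishes the lowest grade of lesion from normal epithelium (14 CIN1 and 24 normal specimens). Interferon-stimulated genes, the antiviral effectors induced by interferon, rose together in CIN1. Their mean over 30 members was 9.53 ± 1.24 (SD, n = 14) against 7.98 ± 0.86 (n = 24), a difference of 1.55 (permutation test, adjusted p = 0.00403) with 12 of 14 CIN1 arrays above the normal mean. Adjusted over the list alone 23 of the 30 members were higher, against 0 when adjusted over all genes tested. MX2, a restriction factor, measured 8.71 ± 1.89 in CIN1 and 6.18 ± 1.52 in normal tissue. IFIT3, an inhibitor of viral translation complexes, measured 10.56 ± 1.69 and 8.19 ± 1.58, and each of these genes had adjusted p = 0.137 in limma. The interferon list also held against the other genes tested, with an estimated correlation between genes (camera, adjusted p = 0.0143), and within array sets (difference 1.53, adjusted p = 0.0198). It differed by 3.71 in set 1 (3 CIN1 and 7 normal arrays, exact permutation p = 0.00833) and by 0.68 in set 2 (8 and 17 arrays, exact permutation p = 0.0952). With the score of other cell types regressed out the difference was 1.33 (adjusted p = 0.014). Genes of T and NK cells averaged 7.02 ± 1.20 in CIN1 and 6.21 ± 0.79 in normal tissue, and those of macrophages and neutrophils 6.39 ± 0.80 and 5.78 ± 0.65 (adjusted p = 0.0645 for each).

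Genes of DNA repair rose by 0.62 as a list of 16 in CIN1 (adjusted p = 0.0468, above the normal mean in 14 of 14 arrays), with 6 members higher adjusted over the list alone and 0 over all genes. The call was lost with an estimated correlation (adjusted p = 0.177), while within array sets the difference was 0.62 (adjusted p = 0.0394). BLM, a RecQ helicase, measured 7.31 ± 0.67 in CIN1 and 6.31 ± 0.93 in normal tissue. FANCI, of the Fanconi pathway, measured 9.87 ± 0.92 and 8.87 ± 0.95. The list of S phase and DNA replication genes differed by 0.83 and did not pass (adjusted p = 0.053), although 16 of 27 members were higher adjusted over the list alone. Its member MCM6, a subunit of the replicative helicase, measured 11.50 ± 0.81 in CIN1 and 10.26 ± 1.10 in normal tissue. Among the reference markers, CDKN2A, which encodes the cell-cycle inhibitor p16 used to stain high-grade lesions, measured 6.91 ± 4.03 against 4.07 ± 2.81 (adjusted p = 0.439). MKI67, the proliferation antigen, measured 8.79 ± 1.36 against 7.34 ± 1.59 (adjusted p = 0.398).

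No single gene was called in CIN1 by limma in the 2-group fit. At an unadjusted p under 0.05 there were 989 genes, and the Wilcoxon rank-sum test called 0 (915 unadjusted). The blocked fit called 1 gene, CRISP2, a cysteine-rich secretory protein, which fell by 3.11 ± 0.62 (SE; adjusted p = 0.0194) and lay below the normal mean in 12 of 14 CIN1 arrays. Without the arrays of low correlation this call was lost too (adjusted p = 0.099 for CRISP2). The DNA repair call depended on single arrays and settings. Its adjusted p was 0.0653 without Normal replicate 24, and without the 8 arrays of low correlation with their own group 0.143, in a range of 0.0394 to 0.177 over all settings.

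Between CIN1 and CIN2 (14 and 22 specimens), the interferon-stimulated genes were lower in the higher grade. Their mean over 30 members fell by 1.33, from 9.53 ± 1.24 to 8.20 ± 0.95 (permutation test, adjusted p = 0.0301), with 20 of 22 CIN2 arrays below the CIN1 mean. Adjusted over the list alone 20 of 30 members were lower, and over all genes 0. IFIT1, which binds viral RNA lacking cap methylation, measured 6.98 ± 2.14 in CIN2 and 9.94 ± 1.76 in CIN1. Its relative IFIT2 measured 9.41 ± 0.97 and 11.07 ± 1.33, each with adjusted p = 0.193 in limma. The 14 CIN1 arrays are those compared with normal tissue above, so this fall is not independent of that rise. The list held with an estimated correlation (adjusted p = 0.0105) and within array sets (difference -1.37, adjusted p = 0.017). It differed by -2.70 in set 1 (3 CIN1 and 6 CIN2 arrays), -0.60 in set 2 (8 and 10) and -1.74 in set 3 (3 and 6). Its adjusted p was 0.0957 with arrays shifted to an equal median and 0.0815 without the arrays of low correlation. It was 0.0756 with the score of other cell types regressed out (difference -1.09). The range over settings was 0.00558 to 0.0957. Genes of T and NK cells averaged 7.02 ± 1.20 in CIN1 and 6.34 ± 0.92 in CIN2.

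S phase and DNA replication genes differed by 0.74 between CIN1 and CIN2 and did not pass (adjusted p = 0.17; 1 of 27 members higher adjusted over the list alone, 0 over all genes). E2F8, an atypical member of the E2F family, measured 10.28 ± 1.02 in CIN2 and 9.03 ± 1.12 in CIN1. CCNE2, cyclin E2, measured 10.09 ± 1.18 and 9.04 ± 0.82. CDKN2A measured 9.37 ± 3.66 in CIN2 and 6.91 ± 4.03 in CIN1 (adjusted p = 1). CXCL14, a chemokine of squamous epithelium, measured 12.54 ± 1.79 and 13.66 ± 0.63 (adjusted p = 1). No gene was called between these grades by limma, either in the 2-group fit (536 genes at an unadjusted p under 0.05) or in the blocked fit (615), and the Wilcoxon test called 0 (557 unadjusted).

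Against normal epithelium (24 specimens), CIN2 (22) had higher expression of cell-cycle genes and of CDKN2A. CDKN2A rose by 5.30 ± 0.93 (SE) from 4.07 ± 2.81 (SD), with 18 of 22 CIN2 arrays above the normal mean (adjusted p = 0.000461), by 5.54 in the blocked fit, and by 4.92 in set 1 and 6.15 in set 2. SYCP2, a component of the synaptonemal complex of meiotic chromosomes, rose by 3.46 ± 0.64 (adjusted p = 0.000794; 3.38 in the blocked fit). TCAM1P, a pseudogene of a testis adhesion molecule, rose by 3.32 ± 0.49 (adjusted p = 0.000137) in 21 of 22 arrays. BRIP1, a DNA helicase, rose by 2.79 ± 0.50 (2.69 in the blocked fit) and HS6ST2, a heparan sulfate sulfotransferase, by 2.66 ± 0.79 (2.69).

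Of 27 genes of S phase and DNA replication, 24 rose in CIN2 and 0 fell (27 adjusted over the list alone). Of 28 mitosis genes 23 rose and 0 fell (28 adjusted over the list alone). As lists they rose by 1.57 each (adjusted p = 0.000207 and 0.00031), with 20 of 22 CIN2 arrays above the normal mean. The rises were 1.47 and 1.50 within array sets (adjusted p = 0.000103 and 0.0013). E2F8 rose by 2.13 ± 0.34 (2.07 in the blocked fit), above the normal mean in 22 of 22 arrays. DTL, an adaptor of a replication-coupled ubiquitin ligase, rose by 2.25 ± 0.39 (2.09), and MCM6 by 1.76 ± 0.31 (1.65). TTK, a kinase of the spindle checkpoint, rose by 2.30 ± 0.43 (2.12), CDK1, the mitotic kinase, by 1.89 ± 0.34 (1.77), and MKI67 by 2.17 ± 0.40 (2.09). Of 16 DNA repair genes 12 rose (13 adjusted over the list alone), among them CHEK1, the checkpoint kinase, by 2.48 ± 0.45 (2.52) and FANCI by 1.75 ± 0.28 (1.74). As a list they rose by 1.12 within array sets (adjusted p = 0.000103). With an estimated correlation the S phase (adjusted p = 0.009), mitosis (0.0308) and DNA repair (0.009) lists held. With array set as a block in the same test mitosis was lost (adjusted p = 0.0626).

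The list of HPV lesion biomarkers, which shares members with the cell-cycle lists, rose by 1.73 (adjusted p = 0.000155; 0.0142 with an estimated correlation) and by 1.64 within array sets. Of its 8 members 5 were higher (6 adjusted over the list alone), STMN1, a microtubule regulator, by 1.42 ± 0.28 (1.33 in the blocked fit). Regulators of DNA methylation and Polycomb rose by 0.58 as a list of 19 (adjusted p = 0.00491, 19 of 22 arrays; adjusted p = 0.209 with an estimated correlation) and by 0.54 within array sets (adjusted p = 0.000542). It had 6 members higher and 0 lower (7 adjusted over the list alone). UHRF1, which recruits the maintenance DNA methyltransferase, rose by 2.13 ± 0.36 (2.04) and HELLS, a chromatin remodeller, by 1.95 ± 0.43 (1.99). Genes of the distal long arm of chromosome 3 (the distal 3q genes), a region often gained in cervical cancer, rose by 0.49 (adjusted p = 0.00996, 17 of 22 arrays; adjusted p = 0.3 with an estimated correlation) and by 0.45 within array sets (adjusted p = 0.00139). RFC4 is also in the S phase list, and gene copy number was not measured. Of 25 members 4 were higher over all genes and over the list alone. These were ECT2, a cytokinesis exchange factor (1.32 ± 0.32; 1.28 in the blocked fit), RFC4, a clamp loader of replication (1.43 ± 0.40; 1.39), ACTL6A, of chromatin remodelling complexes (0.92 ± 0.19; 0.75), and PDCD10 (0.59 ± 0.17; 0.57, adjusted p = 0.215). Germline and meiosis genes rose by 1.08 as a list of 7 (adjusted p = 0.00062; adjusted p = 0.105 with an estimated correlation) and by 0.92 within array sets (adjusted p = 0.00425). There were 2 members higher (3 adjusted over the list alone): SYCP2, and RNF212, whose fold was 0.79 in the 2-group fit and 0.19 in the blocked fit (adjusted p = 0.871).

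Few genes fell in CIN2. CRISP2 fell by 2.65 ± 0.69 (-2.24 in the blocked fit; adjusted p = 0.0178) and EPB41L3, an adaptor between membrane and cytoskeleton, by 2.43 ± 0.60 (-2.52; adjusted p = 0.0114), each below the normal mean in 19 of 22 arrays. F3, tissue factor, fell by 1.67 ± 0.40 (-1.75). KRT13, a keratin of the upper squamous layers, measured 14.90 ± 1.53 in CIN2 and 14.43 ± 3.20 in normal tissue (adjusted p = 0.879). ESR1, the estrogen receptor, measured 11.21 ± 2.00 and 12.34 ± 1.06 (adjusted p = 0.207).

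In total 437 genes were called in CIN2 by limma, 406 higher and 31 lower, 274 of them by 2-fold or more. With arrays shifted to an equal median the split was 307 higher and 118 lower of 425. The blocked fit called 338 (307 higher and 31 lower), of which 282 were also called in the 2-group fit. In set 2 alone 144 genes were called and in set 1 alone, with 6 CIN2 and 7 normal arrays, 0 (767 at an unadjusted p under 0.05).

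CIN3 was compared with CIN2 (40 and 22 specimens) to ask what changes between the higher grades. Genes of matrix proteases and invasion rose as a list of 18, from 6.37 ± 0.93 to 7.25 ± 1.06, a difference of 0.88 or 0.72 relative to the median of all genes (permutation test, adjusted p = 0.0343), with 33 of 40 CIN3 arrays above the CIN2 mean. With an estimated correlation the call was lost (adjusted p = 0.586). Within array sets the difference was 1.08 (adjusted p = 0.00744), 0.33 in set 1 and 1.42 in set 3. In the 2-group fit 4 members were called higher (5 adjusted over the list alone): MMP9, a gelatinase (2.55 ± 0.68), INHBA, the activin A subunit (1.76 ± 0.48), PLAU, urokinase (1.05 ± 0.30), and its receptor PLAUR (1.35 ± 0.36). The blocked fit gave 1.86, 1.02, 0.91 and 1.30 for the same 4 genes and called 0 of them (adjusted p from 0.498 to 0.627), and in set 1 alone the fold of INHBA was -0.35. Genes of macrophages and neutrophils averaged 6.63 ± 0.90 in CIN3 and 6.03 ± 0.74 in CIN2, and those of T and NK cells 6.85 ± 1.23 and 6.34 ± 0.92. Those of Langerhans cells went the other way, 4.07 ± 1.04 and 4.50 ± 1.13.

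Interferon-stimulated genes were 0.89 higher as a list in CIN3 than in CIN2 (adjusted p = 0.0343; 0.73 relative to the median of all genes), S phase genes 0.61 (adjusted p = 0.0368; 0.45) and mitosis genes 0.59 (adjusted p = 0.0424; 0.43), each with adjusted p = 0.586 with an estimated correlation. Within array sets these differences were 0.75, 0.41 and 0.46 and did not pass (adjusted p = 0.134, 0.163 and 0.162). The 2-group fit called 3 of 30 interferon-stimulated genes (13 adjusted over the list alone), 2 of 27 S phase genes (12) and 1 of 28 mitosis genes (13). ISG15, the ubiquitin-like antiviral protein, differed by 1.82 ± 0.50 (1.85 in the blocked fit, adjusted p = 0.483). UBE2C, a mitotic ubiquitin enzyme, differed by 0.68 ± 0.21 (0.58, adjusted p = 0.523). CLSPN, a replication checkpoint adaptor, differed by 0.69 in the 2-group fit and by -0.01 in the blocked fit.

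For CIN3 against CIN2, limma called 478 genes, 326 higher and 152 lower (162 by 2-fold or more), while the median of all genes was itself shifted by 0.16. With arrays shifted to an equal median the split was 126 higher and 298 lower of 424, and after a further quantile normalization 173 and 175 of 348. The blocked fit called 0 genes (1052 at an unadjusted p under 0.05) and shifted the median by 0.05. The 2-group fit with the block called 0 (1446 unadjusted), so these 478 calls cannot be separated from the uneven spread of the grades over array sets. Genes whose fold stayed close to its 2-group size were OLFM1, a secreted glycoprotein (2.28 ± 0.58, and 2.31 in the blocked fit, adjusted p = 0.428), SYNGR3, a synaptic vesicle protein (2.53 ± 0.56, and 2.37, adjusted p = 0.429), and EDN3, endothelin 3 (-3.02 ± 0.80, and -3.07, adjusted p = 0.443). APOC1 went from 2.48 to 0.59 and MYO3A from 2.14 to 0.17. With arrays shifted to an equal median 0 of the 31 lists passed in this comparison, against 13 in the main setting. The list of matrix proteases and invasion was among those lost (adjusted p = 0.111, in a range of 0.00744 to 0.586). With the score of other cell types regressed out its difference was 0.54 (adjusted p = 0.0879). The interferon, S phase and mitosis lists, at 0.73, 0.50 and 0.51, did not pass either (adjusted p = 0.0879, 0.0993 and 0.0993). Regressing out makes differences smaller, so these losses do not show that other cell types account for the rises.

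CIN3 was next compared with normal epithelium (40 and 24 specimens), the widest contrast among the lesions. CDKN2A was the gene with the largest rise, by 6.60 ± 0.68 (SE) in the 2-group fit, to 10.66 ± 2.62 (SD) from 4.07 ± 2.81 (adjusted p = 1.29e-11), with 37 of 40 CIN3 arrays above the normal mean. It rose by 7.20 ± 0.97 in the blocked fit and by 6.24 in set 1 alone. Its normal mean lay near the low-value filter of log2 4, close to background, which leaves the exact fold and its rank uncertain. SYCP2 rose by 5.12 ± 0.55 (4.74 in the blocked fit), HS6ST2 by 4.56 ± 0.55 (4.56), SYNGR3 by 4.70 ± 0.46 (4.42), ABCA17P, a transporter pseudogene, by 4.64 ± 0.62 (4.34) and TCAM1P by 4.79 ± 0.45 (3.65). ELAVL2, a neuronal RNA-binding protein, rose by 4.51 ± 0.62 (4.45).

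**Figure D2:**
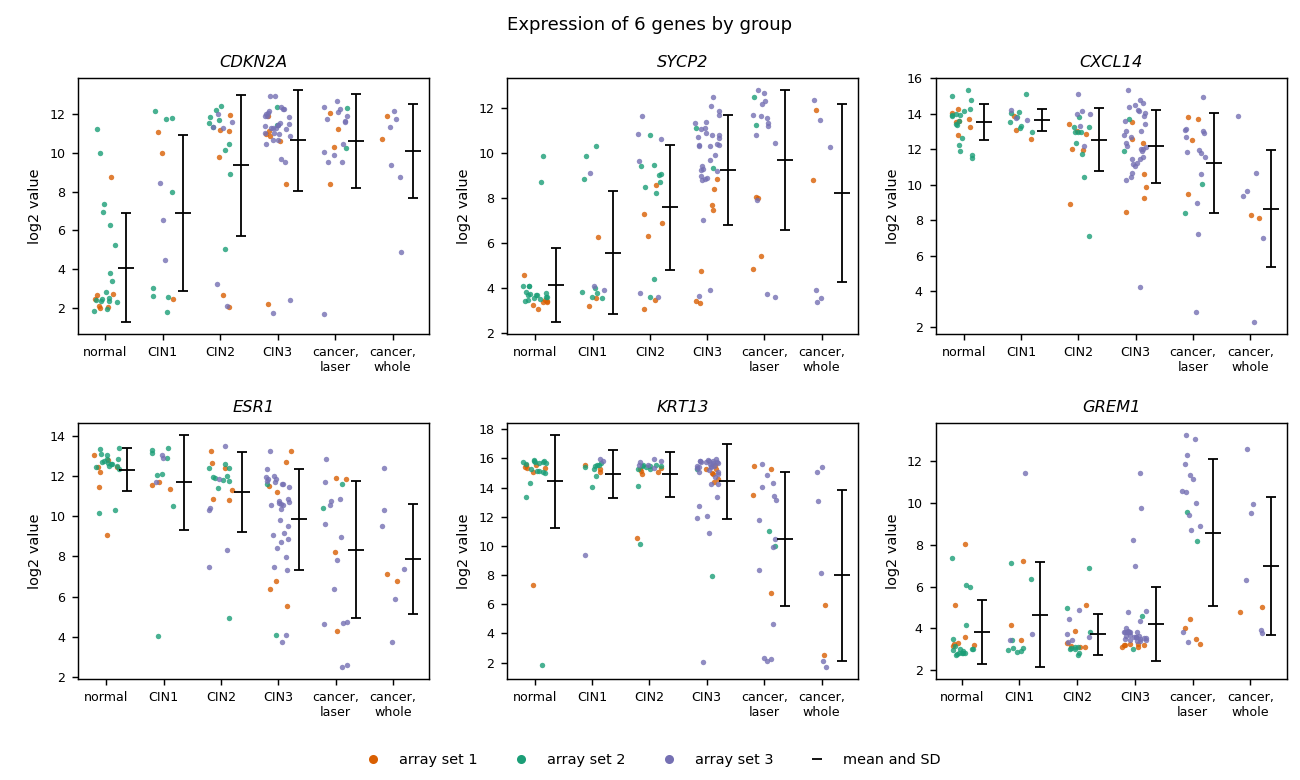
Log2 expression (vertical axis) of CDKN2A, SYCP2, CXCL14, ESR1, KRT13 and GREM1 in each array, by group (horizontal axis) and coloured by array set, with the group mean and SD. CDKN2A averages 4.07 in normal tissue, 6.91 in CIN1, 9.37 in CIN2 and 10.62 in laser-captured cancers, and GREM1 averages 4.21 in CIN3 and 8.57 in laser-captured cancers.

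All 27 S phase genes and all 28 mitosis genes tested were called higher in CIN3 (27 and 28 adjusted over the list alone), and 26 and 28 of them in the blocked fit. As lists they rose by 2.17 and 2.16, or by 1.94 and 1.93 relative to the median of all genes, with 40 of 40 CIN3 arrays above the normal mean (adjusted p = 4.43e-05, from the smallest p the resamples can give). Within array sets, where only 7 and 2 of the 40 CIN3 arrays took part (sets 1 and 2), the rises were 1.69 (adjusted p = 0.000317) and 1.81 (adjusted p = 0.00533). In set 1 alone they were 1.50 and 1.57. The mitosis list was lost with an estimated correlation (adjusted p = 0.0846) and the S phase list was not (adjusted p = 0.0401). With array set as a block in that test the mitosis list passed (adjusted p = 0.0255). MCM2, of the replicative helicase, rose by 2.56 ± 0.26 (2.75 in the blocked fit), DTL by 2.98 ± 0.30 (2.48), AURKA, the mitotic kinase Aurora A, by 2.17 ± 0.25 (1.86) and NUSAP1, a spindle protein, by 2.65 ± 0.31 (2.07). DNA repair genes rose by 1.35 relative to the median of all genes, with 14 of 16 higher (14 adjusted over the list alone; 12 in the blocked fit), FANCI by 2.17 ± 0.21 and EXO1, a mismatch repair exonuclease, by 2.46 ± 0.21 (1.23 in the blocked fit). That list held within array sets (1.25, adjusted p = 0.000132) and with an estimated correlation (adjusted p = 0.0401).

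The distal 3q genes rose by 0.95 in CIN3 (0.71 relative to the median of all genes; adjusted p = 4.43e-05), above the normal mean in 38 of 40 arrays. It rose by 0.95 within array sets (adjusted p = 0.000132), and the call was lost with an estimated correlation (adjusted p = 0.338) but kept with array set as a block in that test (adjusted p = 0.0255). Of 25 members 18 were called higher and 0 lower (21 adjusted over the list alone), and 11 in the blocked fit. ECT2 rose by 2.04 ± 0.25 (1.86 in the blocked fit), RFC4 by 2.41 ± 0.32 (2.18), ACTL6A by 1.54 ± 0.16 (1.08) and CLDN1, claudin 1 of tight junctions, by 1.61 ± 0.28 (1.60). Regulators of DNA methylation and Polycomb rose by 0.58 relative to the median of all genes, with 12 of 19 higher and 2 lower (the same counts adjusted over the list alone; 7 and 0 in the blocked fit). The rise was 0.63 within array sets (adjusted p = 0.00113; adjusted p = 0.389 with an estimated correlation). UHRF1 rose by 2.69 ± 0.30 (2.38), EZH2, the Polycomb methyltransferase, by 1.88 ± 0.26 (1.42) and SUV39H2, a histone H3 methyltransferase, by 1.85 ± 0.27 (1.71). Germline and meiosis genes rose by 1.65 relative to that median, 4 of 7 members (4 adjusted over the list alone; 2 in the blocked fit). That rise was 1.16 within array sets (adjusted p = 0.0164; adjusted p = 0.222 with an estimated correlation). MEI1, of meiotic recombination, rose by 1.87 ± 0.39 (1.71), and RNF212 by 2.40 in the 2-group fit but 0.70 in the blocked fit (adjusted p = 0.0659). The HPV lesion biomarkers rose by 2.36 (7 of 8 members, also over the list alone; 2.09 within array sets, adjusted p = 0.000141; adjusted p = 0.0401 with an estimated correlation).

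Matrix protease genes rose by 0.95 in CIN3 (0.72 relative to the median of all genes; 1.06 within array sets, adjusted p = 0.0233; adjusted p = 0.747 with an estimated correlation). Of 18 members 7 were higher (7 adjusted over the list alone; 4 in the blocked fit). MMP12, the macrophage elastase, rose by 3.41 ± 0.75 (3.84 in the blocked fit), MMP9 by 3.44 ± 0.62 (2.42) and SPP1, osteopontin, by 2.80 ± 0.64 (3.07). Chemokines rose by 1.02 (0.79 relative to the median of all genes; 0.97 within array sets, adjusted p = 0.0271; adjusted p = 0.747 with an estimated correlation). Of 21 members 9 were higher and 2 lower (9 and 2 adjusted over the list alone; 3 and 1 in the blocked fit). CXCL8, a neutrophil attractant, rose by 2.65 ± 0.76 (3.98), whereas CXCL14 fell by 1.37 ± 0.44 (-2.02 in the blocked fit, adjusted p = 0.0302). Genes of macrophages and neutrophils averaged 6.63 ± 0.90 in CIN3 and 5.78 ± 0.65 in normal tissue, those of T and NK cells 6.85 ± 1.23 and 6.21 ± 0.79, and those of B and plasma cells 6.58 ± 1.73 and 5.60 ± 1.15. With the score of other cell types regressed out the matrix protease and chemokine lists each differed by 0.69 (adjusted p = 0.00505 and 0.00209). Within array sets, neither list passed once arrays had been shifted to an equal median (adjusted p = 0.0651 and 0.0845).

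Squamous differentiation genes, which build the cornified upper layers, fell by 1.55 as a list of 33 (-1.79 relative to the median of all genes; adjusted p = 0.0175), with 31 of 40 CIN3 arrays below the normal mean. Within array sets the difference was -2.01 and did not pass (adjusted p = 0.0629; adjusted p = 0.389 with an estimated correlation). The 2-group fit called 13 members lower and 0 higher (14 adjusted over the list alone), and the blocked fit 10. CRISP3, a secreted cysteine-rich protein, fell by 5.65 ± 0.84 (-4.83 in the blocked fit), RPTN, repetin of the cornified envelope, by 3.72 ± 0.82 (-3.84) and DSG1, desmoglein 1, by 3.17 ± 1.04 (-4.78). KRT13 measured 14.42 ± 2.57 against 14.43 ± 3.20 (adjusted p = 0.991). Steroid receptors and genes of the estrogen response fell by 0.87 (-1.11 relative to the median; adjusted p = 0.0162), 6 of 17 lower and 1 higher, also over the list alone, but not within array sets (-0.66, adjusted p = 0.204; adjusted p = 0.389 with an estimated correlation). ESR1 fell by 2.49 ± 0.53 (-2.31 in the blocked fit, adjusted p = 0.0466), below the normal mean in 36 of 40 arrays. GREB1, an estrogen-induced gene, fell by 3.67 ± 0.70 (-2.39, adjusted p = 0.049). EDN3 fell by 3.96 ± 0.73 (-4.07) and UPK1A, a uroplakin, by 4.23 ± 0.90 (-4.16).

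In CIN3 against normal tissue limma called 4108 genes in the 2-group fit, 3143 higher and 965 lower (1589 by 2-fold or more), with the median of all genes shifted by 0.23. After shifting arrays to an equal median the split was 1463 higher and 2275 lower of 3738. The blocked fit called 1143, 886 higher and 257 lower, with a shift of 0.08, and 1037 of these were also called in the 2-group fit. The 2-group fit with the block called 240, and set 1 alone, with 7 arrays on each side, 0 (1150 at an unadjusted p under 0.05).

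**Figure D3:**
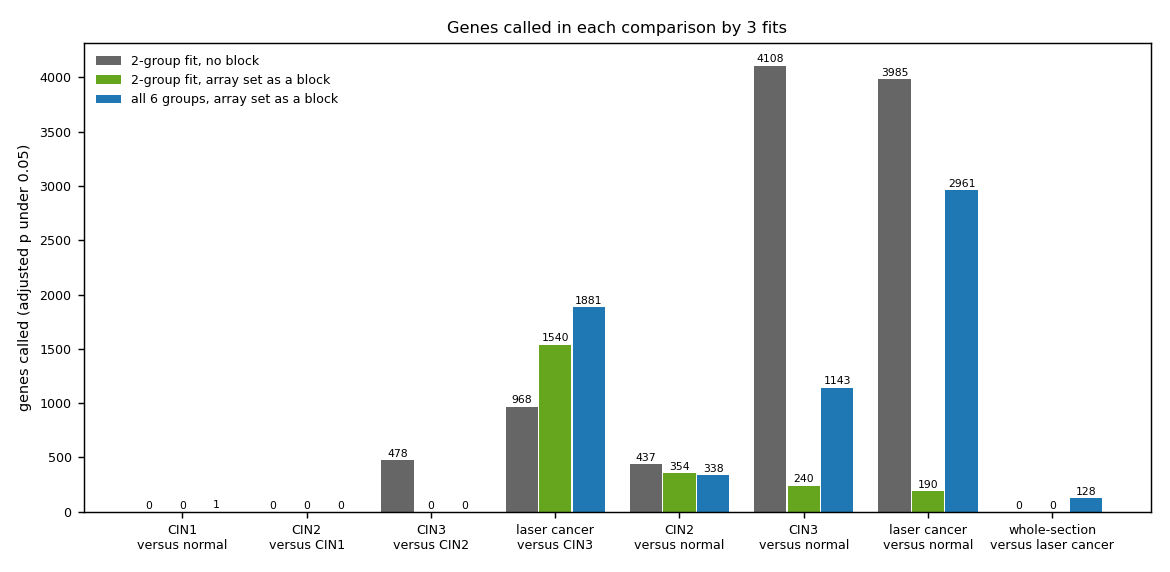
Genes called at an adjusted p under 0.05 (vertical axis) in the 8 comparisons, by the 2-group fit without a block, the 2-group fit with array set as a block, and the fit of all 6 groups with that block (bars). CIN3 against normal tissue goes from 4108 to 240 and 1143, CIN3 against CIN2 from 478 to 0 and 0, and laser-captured cancer against CIN3 from 968 to 1540 and 1881.

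The step to invasion was examined in 20 laser-captured cancers against 40 CIN3 lesions. Both groups had arrays in every array set, with 2 of each in set 2. Some genes of the stroma and of matrix remodelling were higher in the cancers. GREM1, a secreted antagonist of bone morphogenetic proteins, rose by 4.37 ± 0.67 (SE), to 8.57 ± 3.52 (SD) from 4.21 ± 1.79 (adjusted p = 3.83e-05), with 15 of 20 cancers above the CIN3 mean. Its rise in the blocked fit was 4.50. FN1, fibronectin, rose by 3.64 ± 0.64 (19 of 20 cancers; 5.41 in set 1 and 3.57 in set 3), INHBA by 3.63 ± 0.66 (18 of 20; 3.62 and 4.03), SULF1, an extracellular sulfatase, by 3.49 ± 0.70, COL8A1, a collagen, by 3.23 ± 0.70 and DPT, dermatopontin of the matrix, by 3.00 ± 0.61.

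Of 25 genes of fibroblasts and collagens, 10 rose and 1 fell (13 and 1 adjusted over the list alone; 12 and 1 in the blocked fit). The list rose by 1.23 (adjusted p = 0.0216; 16 of 20 cancers) and by 1.28 within array sets (adjusted p = 0.00533), 2.08 in set 1 and 1.16 in set 3, but was lost with an estimated correlation (adjusted p = 0.305). TNFAIP6, a hyaluronan-binding protein, rose by 2.94 ± 0.36 in 19 of 20 cancers, FAP, the fibroblast activation protein, by 2.67 ± 0.52 and COL5A2 by 2.34 ± 0.47. Smooth muscle genes rose by 1.42 as a list of 8 (adjusted p = 0.00093; 18 of 20 cancers; 1.47 within array sets; adjusted p = 0.0822 with an estimated correlation). It had 4 members higher (6 adjusted over the list alone), ACTA2, smooth muscle actin (1.83 ± 0.48), ACTG2, its enteric relative (2.08 ± 0.47), MYH11, smooth muscle myosin (1.90 ± 0.51), and TAGLN, transgelin (2.40 ± 0.69). The matrix protease list rose by 1.11 (adjusted p = 0.00868; 14 of 20 cancers; 1.14 within array sets, adjusted p = 0.00114; adjusted p = 0.178 with an estimated correlation). Of 18 members 3 were higher (8 adjusted over the list alone; 4 in the blocked fit), with ADAM12, a disintegrin metalloprotease, at 2.80 ± 0.63 and MMP3, stromelysin 1, at 2.16 ± 0.49. Regulators of epithelial and mesenchymal state differed by 0.48 as a list of 14 (adjusted p = 0.0658) and passed within array sets (0.52, adjusted p = 0.00646; adjusted p = 0.842 with an estimated correlation). With the score of other cell types regressed out the difference was 0.16 (adjusted p = 0.348). Members went both ways, 2 up and 1 down (4 and 1 adjusted over the list alone): ZEB2, a repressor of epithelial genes, rose by 1.86 ± 0.50, CDH2, N-cadherin, by 1.52 ± 0.41, and OVOL2, an epithelial transcription factor, fell by 0.97 ± 0.22.

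Squamous differentiation genes fell by 2.44 in the cancers (adjusted p = 0.00263), from 9.68 ± 2.06 to 7.24 ± 2.08, with 17 of 20 cancers below the CIN3 mean. Of 33 members 21 fell and 0 rose (25 adjusted over the list alone; 22 in the blocked fit). The list fell by 2.42 within array sets (adjusted p = 0.000775), -0.59 in set 1 and -2.94 in set 3, and was lost with an estimated correlation (adjusted p = 0.178). CRNN, cornulin of the upper epithelium, fell by 6.42 ± 1.21, CLCA4, a chloride channel regulator, by 4.78 ± 0.86, SPRR3, of the cornified envelope, by 3.99 ± 0.91 and KRT13 by 3.96 ± 0.90 (adjusted p = 0.00385; 16 of 20 cancers below the CIN3 mean). Genes of stress keratins and alarmins fell by 1.29 as a list of 11 (adjusted p = 0.0216; 13 of 20 cancers; 1.33 lower within array sets, adjusted p = 0.0142; adjusted p = 0.305 with an estimated correlation). Of its members 6 were lower (7 adjusted over the list alone; 4 in the blocked fit), among them LCN2, lipocalin 2 (-2.36 ± 0.56), and the calprotectin subunit S100A9 (-2.10 ± 0.45).

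A second group of genes that fell encodes products of columnar, secretory epithelium. That list of 22 fell by 1.70 (adjusted p = 0.00579; 16 of 20 cancers) and by 1.77 within array sets (adjusted p = 0.00116), -0.53 in set 1 and -2.17 in set 3, with adjusted p = 0.305 with an estimated correlation. Of its members 8 fell and 0 rose (8 adjusted over the list alone; 7 in the blocked fit). PIGR, the polymeric immunoglobulin receptor, fell by 5.28 ± 1.05, TFF3, a trefoil peptide of mucus, by 4.39 ± 1.04, MUC5B, a gel-forming mucin, by 4.16 ± 1.00 and SCGB2A1, a secretoglobin, by 3.73 ± 0.95. Outside the list, BPIFB1, a secreted airway and mucosal protein, fell by 5.57 ± 1.20, CYP4B1, a cytochrome P450, by 5.10 ± 0.94 and FCGBP, a mucus protein that binds IgG, by 4.71 ± 0.73. CDKN2A measured 10.62 ± 2.43 in the cancers and 10.66 ± 2.62 in CIN3 (adjusted p = 0.98), and TOP2A, the S phase and mitosis topoisomerase, 11.83 ± 1.24 and 11.94 ± 1.01 (adjusted p = 0.896).

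**Figure D4:**
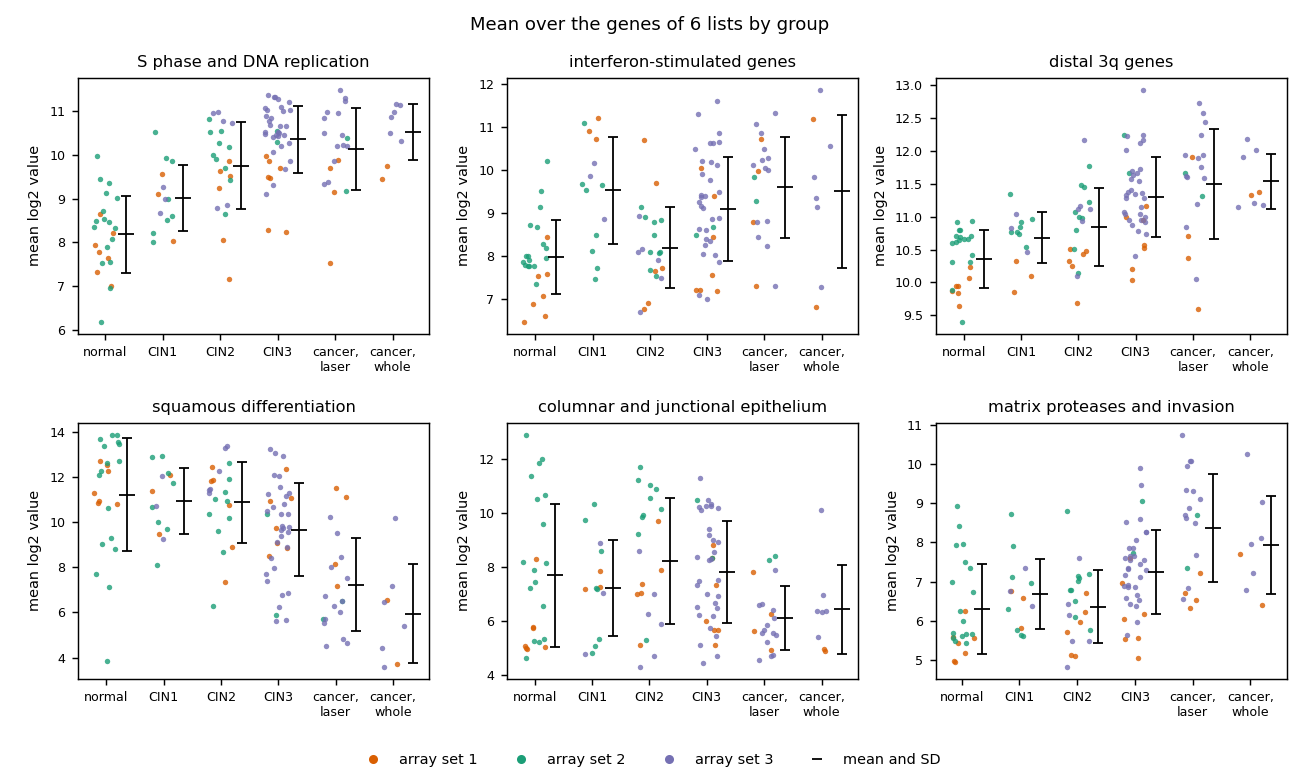
Mean log2 value over the tested genes of 6 lists (vertical axis) in each array, by group (horizontal axis) and coloured by array set, with the group mean and SD. S phase genes average 8.19 in normal tissue and 10.36 in CIN3, squamous differentiation genes 9.68 in CIN3 and 7.24 in laser-captured cancers, and interferon-stimulated genes 7.98 in normal tissue, 9.53 in CIN1 and 8.20 in CIN2.

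Limma called 968 genes between laser-captured cancer and CIN3, 276 higher and 692 lower (613 by 2-fold or more). The split was 602 higher and 594 lower of 1196 with arrays shifted to an equal median, and 865 and 1016 of 1881 in the blocked fit, which kept 937 of the 968. The 2-group fit with the block called 1540 genes, set 3 alone 1322 and set 1 alone, with 4 cancers and 7 CIN3 lesions, 6. The rise of the smooth muscle list was 0.64 when all probe sets of a gene were averaged. With the score of other cell types regressed out it was 0.92, and that of the matrix protease list 0.67 (adjusted p = 0.036). The mean over the genes of fibroblasts, endothelium, T and NK cells, and macrophages and neutrophils was 7.98 ± 1.27 in the cancers and 7.41 ± 0.98 in CIN3. With it as a covariate 1140 genes were called, 153 higher and 987 lower.

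Laser-captured cancers (20) were also set against normal epithelium (24). CDKN2A rose by 6.55 ± 0.77 (SE; 7.11 in the blocked fit, 7.29 in set 1 alone; adjusted p = 5.22e-08), above the normal mean in 19 of 20 cancers. CTHRC1, a secreted collagen-associated protein, rose by 6.03 ± 0.72 (6.15 in the blocked fit) and ZIC2, a zinc finger transcription factor of early development, by 5.79 ± 0.45 (5.28), each in 20 of 20 cancers. Squamous differentiation genes fell by 4.00 (-4.18 relative to the median of all genes, which was shifted by 0.18; adjusted p = 0.000103), with 29 of 33 members lower (31 adjusted over the list alone; 30 in the blocked fit). CRNN fell by 9.34 ± 1.14 (-9.04), CRISP3 by 8.75 ± 0.70 (-7.99), MAL, a membrane-trafficking proteolipid, by 6.58 ± 0.87 (-6.81) and TMPRSS11B, a transmembrane serine protease, by 6.64 ± 1.01 (-7.18). The list lay below the normal mean in 19 of 20 cancers and fell by 3.298 within array sets (adjusted p = 0.00884; adjusted p = 0.121 with an estimated correlation).

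The matrix protease list rose by 2.06 in the cancers (1.88 relative to the median of all genes; adjusted p = 7.75e-05; 20 of 20 cancers), with 12 of 18 members higher (13 adjusted over the list alone; 12 in the blocked fit), and by 1.31 within array sets (adjusted p = 0.0068; adjusted p = 0.238 with an estimated correlation). INHBA rose by 4.96 ± 0.68 (4.00 in the blocked fit), MMP12 by 4.94 ± 0.86 (5.35) and PLAUR by 3.01 ± 0.51 (2.98). Interferon-stimulated genes rose by 1.62 (1.43 relative to that median; adjusted p = 7.75e-05; 18 of 20 cancers; 1.68 within array sets, adjusted p = 0.00641; adjusted p = 0.238 with an estimated correlation). Of 30 members 22 were higher (24 adjusted over the list alone; 17 in the blocked fit). With the score of other cell types regressed out the matrix protease rise was 1.21 (adjusted p = 0.00189) and the interferon rise 1.24 (adjusted p = 0.00114). Genes of macrophages and neutrophils averaged 6.99 ± 1.05 in the cancers and 5.78 ± 0.65 in normal tissue, and those of T and NK cells 6.88 ± 1.26 and 6.21 ± 0.79. IFI44L rose by 4.31 ± 0.72 (3.75), and USP18, a negative regulator of interferon signalling, by 2.43 ± 0.29 (1.97).

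Genes of B and plasma cells rose by 1.60 in the cancers (1.42 relative to the median; adjusted p = 0.00246; 16 of 20 cancers; 1.45 within array sets, adjusted p = 0.00942; adjusted p = 0.463 with an estimated correlation). Of 12 members 7 rose (8 adjusted over the list alone), IGHM, the heavy chain of IgM, by 3.56 ± 0.92 (4.57 in the blocked fit). The list differed by 0.37 in set 1 alone, and its adjusted p was 0.116 with the score of other cell types regressed out (range 0.000439 to 0.463). Langerhans cell genes fell by 0.95 (-1.13 relative to the median; adjusted p = 0.0121; 14 of 20 cancers), 2 of 7 members, also over the list alone: FCER1A, an IgE receptor chain (-2.39 ± 0.56), and CD207, langerin (-2.05 ± 0.64). Within array sets the Langerhans list differed by -0.93 (adjusted p = 0.0526; adjusted p = 0.358 with an estimated correlation). S phase genes rose by 1.96 (1.77 relative to the median), 26 of 27 members (27 adjusted over the list alone), and by 1.34 within array sets (adjusted p = 0.00884; adjusted p = 0.121 with an estimated correlation). The columnar list differed by -1.58 in the 2-group test but by 0.21 within array sets (adjusted p = 0.877).

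Against normal tissue limma called 3985 genes in the cancers, 2652 higher and 1333 lower (2579 by 2-fold or more), or 1908 and 2097 of 4005 with arrays shifted to an equal median. The blocked fit called 2961, 1814 higher and 1147 lower, 2438 of them also called in the same direction in the 2-group fit. The 2-group fit with the block, which rests on 4 cancers and 7 normal arrays of set 1 and 2 cancers and 17 normal arrays of set 2, called 190.

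The last comparison set the 8 whole-section cancers against the 20 laser-captured ones. These are different specimens, so an effect of dissection cannot be told apart from differences between tumours. In limma's 2-group fit 0 genes were called (605 at an unadjusted p under 0.05), by the Wilcoxon test 0 (608 unadjusted) and by the 2-group fit with the block 0 (872 unadjusted). The blocked fit, which takes its spread from all 6 groups, called 60 genes higher and 68 lower in whole sections. If cancers vary more than the other groups, that spread is too small here and the p-values too low. No label splits were made for the blocked fit. PTPRZ1, a receptor tyrosine phosphatase, fell by 5.75 ± 0.85 (SE; limma adjusted p = 7.1e-06) and PI3, the epithelial protease inhibitor elafin, by 4.07 ± 0.74, each below the laser-captured mean in 7 of 8 whole sections. The epithelial serpins SERPINB13 (-4.81 ± 0.85), SERPINB4 (-4.76 ± 1.10) and SERPINB3 (-4.25 ± 0.68) and the cornified envelope genes SPRR1A (-4.52 ± 1.11) and SPRR1B (-4.52 ± 0.99) were lower in the same fit, and GPR160, an orphan receptor (3.53 ± 0.79), TRIM36, a ubiquitin ligase (2.89 ± 0.51), and HAPLN1, a hyaluronan link protein (2.33 ± 0.48), were higher.

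No list passed between whole sections and laser captures (exact permutation, 3 of 31 at an unadjusted p under 0.05). Stress keratins and alarmins differed by -2.58 (exact permutation adjusted p = 0.358), below the laser-captured mean in 6 of 8 whole sections, with 0 of 11 members called and 4 lower adjusted over the list alone. Squamous differentiation differed by -1.29 (exact permutation adjusted p = 0.473; 7 of 8 below), with 0 of 33 called and 1 adjusted over the list alone. Stromal scores were no lower in the captures: fibroblasts and collagens averaged 10.03 ± 1.89 in laser captures and 9.54 ± 1.37 in whole sections, smooth muscle 7.93 ± 1.63 and 7.35 ± 1.11, and endothelium 6.84 ± 1.48 and 6.51 ± 0.73. CDKN2A measured 10.11 ± 2.44 in whole sections and 10.62 ± 2.43 in laser captures, and MKI67 9.56 ± 1.01 and 9.51 ± 1.31. The difference between 3 prime and 5 prime control probe sets, which grows as RNA breaks down or is shortened in amplification, was 4.73 ± 1.05 in whole sections and 6.16 ± 2.02 in laser captures. Without the arrays of low correlation the blocked fit called 34 genes.

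Of the 31 lists, 6 passed in no comparison, in the 2-group permutation test or within array sets: p53 targets, endothelium, hypoxia and glycolysis, Notch and Wnt signalling, immediate early genes, and melanocytes, the last with 1 member tested. Their smallest adjusted p in the 2-group test ranged from 0.0945 for the immediate early genes to 0.414 for the p53 targets, and within array sets from 0.0818 for hypoxia and glycolysis to 0.513 for the p53 targets.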

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

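The patterns weighed below, and their tests, were chosen only after the results had been seen; each prediction was written before its test was run, except for the values in set 3 alone, which were already known. Among the 8 whole-section cancers, 54 scores and genes were screened for 1 array far from the others, and 5 values met the rule. The highest columnar score was 10.09 with the next at 6.94, the lowest MHC class II score was 7.17 with the next at 9.54, and the highest fibroblast score was 12.5 with the next at 10.14. The highest score of epithelial and mesenchymal regulators was 10.66 with the next at 9.41, and the lowest CDKN2A value was 4.9 with the next at 8.74.

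Random splits of the same arrays, made without regard to array set, compare the number of calls with chance. The real labels called 478 genes for CIN3 against CIN2 (highest of the other splits 83), 968 for laser-captured cancer against CIN3 (1.3e+02), 4108 for CIN3 against normal tissue (209) and 3985 for laser-captured cancer against normal tissue (0), and in each of these 1 of 100 splits, the real one, reached that number. For CIN2 against normal tissue 437 genes were called, the highest other split called 1857, and 2 of 100 reached 437. For CIN1 against normal tissue (0; highest other 50), CIN2 against CIN1 (0; 0) and whole-section against laser-captured cancer (0; 100) the real number was 0, which all 100 splits must reach, so the splits decide nothing there. With splits made within array sets and no block, the highest other split called 660 genes for CIN3 against CIN2 (median 152; 5 of 100 reached 478), so chance is not excluded there. The same splits gave a highest of 3932 and a median of 2983 for CIN3 against normal tissue, and 3847 and 2211 for laser-captured cancer against normal tissue, with 1 of 100, the real one, as large in each. There the 31 CIN3 arrays and the 14 laser-captured cancers of set 3 kept their labels, because set 3 holds no normal array. Such splits retain most of the real grouping, so they do not give the number of calls expected by chance. With splits made within array sets and array set as a block, the real labels called 1540 genes for laser-captured cancer against CIN3 (highest other 75), 354 for CIN2 against normal tissue (31) and 240 for CIN3 against normal tissue (43), and 1 of 100 splits, the real one, was as large in each. For laser-captured cancer against normal tissue they called 190, the highest other split 243, and 2 of 100 were as large. For CIN3 against CIN2 they called 0 and the highest other split 460.

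The first pattern weighed is the large number of genes that differed between CIN3 and normal tissue where array set and group coincide: 4519 in sets 2 and 3. If array set were the whole cause, set 1, which holds 7 arrays of each group, should show no shift in the same direction. The median of these genes in set 1, in the direction called, was 0.18 (exact one-sided permutation p = 0.00495) against 0.91 in sets 2 and 3, and 69.8 percent had the same direction. Differences between array sets may thus make up part of the fold but are not likely the whole of it. With the 3 prime to 5 prime RNA measure as a covariate 95.1 percent of the genes were still called, so this measure is not likely the whole cause either.

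The second pattern is the rise of fibroblast and matrix genes in laser-captured cancers over CIN3. It might reflect more cells of every non-epithelial kind in the cancer captures, or a change confined to part of the stroma. The fibroblast score rose by 0.92 more than the mean of the scores of endothelium, T and NK cells, B and plasma cells, and macrophages and neutrophils (permutation within array sets, p = 0.00095). This gap cannot exclude an equal rise of every cell type, because the scores start at unlike distances from background. In CIN3 they were 8.81 for fibroblasts, 6.45 for endothelium, 6.85 for T and NK cells, 6.58 for B and plasma cells and 6.63 for macrophages and neutrophils. Smooth muscle genes, left out of the mean of the other scores, rose by 1.47 within array sets, against 1.28 for fibroblasts, so the change is not particular to fibroblasts and more stroma in the captures is not excluded. In set 3 alone the rise was 1.16 (p = 0.0197), so array set is not likely the cause.

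The third pattern is the fall of secretory genes from CIN3 to laser-captured cancer. In set 3 alone the columnar score differed by -2.17 (p = 0.00038), so array set is not likely the cause. Columnar cells in part of the CIN3 captures could give the same fall. The 22 genes varied together among CIN3 arrays: their median pairwise correlation over 31 CIN3 arrays was 0.46, against a 95th percentile of 0.06 over 10000 random lists. Other lists of related genes varied together too, by another measure, the correlation that camera estimates in the fit of cancer against CIN3. It was 0.639 for mitosis and 0.473 for squamous differentiation, values not on the scale of 0.46. Variation together is thus not particular to the columnar list. The value does not tell columnar cells from a change within squamous cells, and the source is left open.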

How the results depend on the processing

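Tests with array sets and without single arrays were chosen only after the results had been seen. Named genes were tallied once for each comparison that named them. A gene called in the main setting counted as kept if called again in the same direction. An uncalled gene counted as kept if it stayed uncalled, whatever its direction. So counted, 248 were kept with eBayes trend and robust, 247 with the RNA quality covariate, 242 after a further quantile normalization, 236 with arrays shifted to an equal median, 198 in the fit of all 6 groups with the array-set block and 167 in the 2-group fit with it. In set 1 alone, with fewer arrays, 41 were kept, among them genes uncalled in both fits, 180 were weaker and 7 reversed. With the 2-group block and without Normal replicate 24, 95 were kept and 56 were weaker. Signal over background limits genes near the floor, and the filter keeps genes that lie there in a whole group, such as CDKN2A (4.07) and SYCP2 (4.11) in normal tissue and GREM1 (4.21) in CIN3. Where counts changed, the cause was not tested.

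For CIN1 against normal tissue limma called 1 gene with all 6 groups in 1 fit, 1 with the block added (0 without the arrays of low correlation), and 12 in set 1 alone, against 0. For CIN2 against CIN1 array weights gave 7, against 0. For CIN3 against CIN2 (478) no low-value filter gave 1270, the strict filter 271, array weights 2034, set 3 alone 1, and set 1 alone, the 2-group block, that block with an equal median, and the fit of all 6 groups with the block, with or without the arrays of low correlation, 0 each. For laser-captured cancer against CIN3 (968) array weights gave 1845, all 28 cancers 1501 and with the block 2421, the 2-group block 1540 and with an equal median 1657, all 6 groups with the block 1881 and without the arrays of low correlation 2415, and set 1 alone 6. For CIN2 against normal tissue (437) array weights gave 1890, set 2 alone 144 and set 1 alone 0. For CIN3 against normal tissue (4108) the 2-group block gave 240, with an equal median 174, without Normal replicate 24 275, all 6 groups with the block 1143, without the arrays of low correlation 1237, and set 1 alone 0. For laser-captured cancer against normal tissue (3985) array weights gave 6210, the 2-group block 190, with an equal median 185, without Normal replicate 24 254, with all 28 cancers 565, and set 1 alone 10. For whole-section against laser-captured cancer (0) all 6 groups in 1 fit gave 45, with the block 1.3e+02 (60 higher and 68 lower), and without the arrays of low correlation 34. The cause was not tested.

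Lists called in CIN1 against normal tissue went from 2 to 1 with an equal median, with or without permutation within array sets, and with camera. They also went to 1 with the mean of all probe sets, the cell-type score regressed out, and without Normal replicate 24 or the arrays of low correlation. For CIN2 against CIN1 they went from 1 to 0 with an equal median and without the arrays of low correlation. For CIN3 against CIN2 they went from 13 to 0 with an equal median, 0 with camera and 7 with the mean of all probe sets. They went to 1 with the cell-type score regressed out, 1 within array sets and 2 there with an equal median. For CIN2 against normal tissue they went from 7 to 11 with an equal median and 4 with camera, and for CIN3 against normal tissue from 19 to 3 with camera, 9 within array sets and 9 there with an equal median. With camera they went from 6 to 0 for laser-captured cancer against CIN3 and from 21 to 0 for laser-captured cancer against normal tissue. Camera compares list genes with all other genes tested, a different question from that of the permutation test. The cause was not tested.

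The columnar list in laser-captured cancer against normal tissue turned from -1.58 to 0.21 within array sets and 0.10 there with an equal median. For CIN3 against CIN2 in set 1 alone CLSPN turned to -0.23, INHBA to -0.35, MYO3A to -0.25 and USP18 to -0.036, and CLSPN also to -0.087 with the 2-group block and an equal median, -0.006 with all 6 groups and the block, and -0.016 without the arrays of low correlation. EVPL turned to 0.015 in set 1 alone for laser-captured cancer against CIN3. CCL4 turned to -0.17 with the 2-group block and an equal median and to -0.037 in set 1 alone for CIN3 against normal tissue, and FCRL5 to -0.037 in set 1 alone for laser-captured cancer against normal tissue. The cause was not tested.

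The labels give groups the same replicate numbers. With a replicate block 22 genes were called for CIN3 against CIN2, 323 for laser-captured cancer against CIN3 and 663 for CIN2 against normal tissue. Whether samples of equal number are pairs was not settled. Their correlations ranged from -0.402 to 0.672, with medians from -0.003 for CIN1 and laser-captured cancer to 0.212 for normal tissue and CIN3. In 5 of 20 pairs for laser-captured cancer and CIN3, and 1 of 14 for CIN1 and normal tissue, the best correlation was with their own number. Array set was not removed from these correlations, and the lowest numbers of each group lay in set 1. For whole-section against laser-captured cancer no paired analysis was possible, because these groups share no number. The cause was not tested.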

Other observations

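The tests in this part were chosen only after the first results had been seen. Gene families, formed from the letters that open a symbol with 10 or more genes tested, gave 141 families with 3751 genes, compared by permutation within array sets. Such a family can also hold genes that share only the opening letters. Between CIN3 and laser-captured cancer 16 families differed. Collagen genes (COL, 32 genes) rose by 0.96 (adjusted p = 0.000705), with 12 members higher in the 2-group fit and 16 in the blocked fit. Mucins (MUC, 10 genes) fell by 1.71 (adjusted p = 0.00094), keratins (KRT, 23) by 1.42 (adjusted p = 0.00106) and kallikreins (KLK, 10), the proteases of epithelial shedding, by 1.57 (adjusted p = 0.00786). Ribosomal proteins fell by less: RPL genes (40) by 0.28 (adjusted p = 0.0116), with 9 lower in the 2-group fit and 13 in the blocked fit, and RPS genes (32) by 0.24 (adjusted p = 0.00846), with 5 and 10 lower. NDUFA genes (12), subunits of mitochondrial complex I, fell by 0.53 (adjusted p = 0.0231), with 6 lower in the 2-group fit and 7 in the blocked fit. Without regard to array sets the RPS family did not pass (adjusted p = 0.1), and the others named here did.

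In CIN2 against normal tissue 8 families differed, among them MCM (11 genes, including those of replication licensing and the helicase) by 1.09 and KIF (27 genes, kinesins) by 0.59, CEP (35 genes, centrosome) by 0.44 and NUP (24 genes, nuclear pore) by 0.47 (adjusted p = 0.00188, 0.0107, 0.00188 and 0.022). Without regard to array sets MCM passed (adjusted p = 0.0226), and KIF, CEP and NUP did not (adjusted p = 0.0698, 0.102 and 0.0698). For CIN3 against normal tissue the 5 were RAD (0.49), MCM (1.37), CDC (0.67), CEP (0.53) and KIF (0.69), with adjusted p from 0.00192 to 0.0382. In laser-captured cancer against normal tissue 2 families differed, IRF (10 genes, among them transcription factors of interferon responses, 0.76, adjusted p = 0.03) and the CCL chemokines (11 genes, 1.07, adjusted p = 0.0337).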
